A study of Bacillus subtilis subsp. subtilis str. 168 with 12 samples.

How the data were processed

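Total RNA libraries of 12 cultures of Bacillus subtilis 168 were analysed in 4 groups of 3 (WT, F91L, Q150W and yerA-KO), taken from the sample titles. The labels describe triplicates of a single clone and do not state that the cultures are independent clones, so p-values measure the spread between these cultures. The deposited read counts per gene were used as given, and the authors' processing notes name cutadapt, Bowtie2 2.2.6, HTSeq 0.6.1p1, DESeq2 and SAMtools 0.1.19, per the submitters' processing notes, without roles. The deposited FPKM values, per the file headers, equalled the count divided by gene length and by the library's summed counts in 100% of cells, within a tolerance of 0.0051. Gene length in bases was taken from the deposited column of gene sizes, per the file headers. The genome build was not given in the sources used here, so no coordinates are printed. Gene names were matched to the reference table of assembly ASM904v1 (4536 of 4536 names matched), and 12 names carried by more than 1 gene were kept out of the gene lists. Whether counting used strand was not given in the sources used here, so reads of overlapping or antisense genes cannot be assigned with certainty.

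The data came as 2 tables, one with 9 libraries (WT, F91L, Q150W) and one with 6 (yerA-KO and WT). The WT counts were identical in 100% of genes between the tables, and each comparison was made within its own table. No pair of replicates agreed within sampling noise (chi-square per degree of freedom 31.6 to 2695), so each library was counted once. Depth ranged from 4952279 to 16665856 counts per library.

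Genes with a mean FPKM of at least 1 over a table were tested, 3991 of 4536 genes in the larger table and 3764 in the other. Before the data were examined, the groups, the test, the 34 gene lists, the rule for genes named and most of the other settings tried were fixed. The test planned then was limma on log2(FPKM + 1), with edgeR in its place if the files held counts, which they did. The main test was therefore edgeR's quasi-likelihood test with TMM scaling and 1 mean per group, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05 (R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0). The biological coefficient of variation was 0.409 in the larger table and 0.399 in the other. The procedure was tested on simulated data with 200 changed genes. It recovered 12% of 2-fold and 68% of 4-fold changes for F91L against WT (3991 genes), 6% and 78% for Q150W against WT (3991 genes), 7% and 73% for yerA-KO against WT (3764 genes) and 3% and 63% for Q150W against F91L (3991 genes). False calls made up 4.76%, 6.67%, 5.88% and 4.35% of calls in these comparisons, in that order. With 200 changed genes, simulated 2-fold changes were therefore mostly missed. The real comparisons called 1982, 1907, 1553 and 330 genes, in the same order, and more calls ease the adjusted threshold. The simulated recovery therefore does not give the power of the real tests.

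Gene lists covered growth state, cell types of a Bacillus culture, prophages, the purine pathways and the neighbours of yerA, and 713 of 776 list members matched a name in the files. Lists with at least 4 tested members were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and also with an estimated correlation and with fry. camera compares a list with the other genes, and fry tests whether its genes move on balance one way.

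Genes named in the text follow the rule fixed then. In each comparison with WT it takes yerA, then the 10 largest and 10 smallest log2 fold changes among genes past the threshold with a mean FPKM of at least 10 in the higher group and no overlap between the groups (5 and 5 for Q150W against F91L), then up to 4 members with the smallest adjusted p of each list described. After the values and their stability had been seen, named list members were narrowed to those past the threshold in lists past camera, or in the lists of yerA neighbours and purine salvage. The wider choice of 612 named values would have held 79 reversals among 13744 re-tests, against 4 among 7510 for the 333 values kept, yerA left out of both, so the stability of the named genes is that of a selected set. Manganese, maltodextrin, gluconeogenesis, glycine cleavage, trehalose, pyruvate dehydrogenase and aminoacyl-tRNA synthetase genes in the closing part were also chosen after their values were seen.

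Where a group held no count of a gene, the fold is a lower bound against a floor of 3 counts over the group, and with 1 to 3 counts the ratio is given with an exact 95% binomial counting interval. Floors and intervals cover counting error only. Values of yerA were also compared with exact two-sided permutation tests on log2(FPKM + 1), whose smallest p is 0.1 for 3 against 3. Other settings fixed beforehand were other pseudocounts (0.1 and 5), no filter or a mean FPKM of 10, median-of-ratios scaling, quantile normalization, a replicate block, only the compared groups, no dispersion trend, library weights, DESeq2, a fold change of at least 2 and leaving out each library. Alternatives added after seeing the data were limma on log2(FPKM + 1), TMM without ssrA, rnpB and scr, library totals, upper-quartile scaling, a single fit of all 12 libraries, genes of at least 500 bases, and removal of a length trend from the list tests.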

Results

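Total RNA of Bacillus subtilis 168, a Gram-positive soil bacterium, was sequenced from 12 cultures in 4 groups of 3. The groups were the unmodified strain (WT), a strain carrying the F91L substitution and a strain carrying the Q150W substitution in the protein of Bsu06560 (yerA), and a strain labelled as a yerA knockout (yerA-KO). The yerA gene encodes a protein of the adenine deaminase family. Cultures were diluted to an OD600 of about 0.02 in 15 mL of LB medium, grown at 37 °C and harvested at an OD600 of about 0.8, which the labels call early exponential. The question posed by the design was how the transcriptome of each modified strain differed from that of WT, so each was compared with WT, and Q150W was compared directly with F91L. The labels do not say which cultures were grown together, so no difference between groups given here separates genotype from growth stage. Counts summed over genes ranged from 4952279 to 9971555 per library in WT, from 8612817 to 15003249 in F91L, from 10719894 to 16665856 in Q150W and from 13312541 to 14237894 in yerA-KO.

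The make-up of the libraries differed between the groups before any gene was tested. The transfer-messenger RNA gene ssrA, whose product rescues stalled ribosomes, took 22.1% ± 2.98 (SD, n = 3) of the counts in WT, 10.2% ± 2.03 in F91L and 7.82% ± 2.39 in Q150W. In the libraries labelled yerA-KO it took 5.29%, 6.08% and 56.2%, so replicate 3 stood apart from the rest of its group. Replicate 1 of F91L also stood apart, with a chi-square per degree of freedom of 651 and 678 to the other 2 libraries, which had 61.0 between them, and adeC at 121 FPKM against 38.8 and 37.3. The same figure was 390 and 471 for Q150W replicate 3 (44.6 between the others) and 254.5 and 147.5 for WT replicate 2 (31.6). Scaling factors (TMM) in the table of WT, F91L and Q150W were 0.572 to 0.591 in WT, 1.28 to 1.84 in F91L and 1.05 to 1.26 in Q150W. Scaling by library totals in place of TMM moved the median log2 fold change of all genes by 1.37 in F91L, 1.00 in Q150W, 0.30 in yerA-KO and -0.37 between Q150W and F91L. Upper-quartile scaling moved it by 0.19 in F91L and 0.16 in Q150W, and quantile normalization by 0.11 in Q150W and in the direct comparison. TMM without ssrA, rnpB and scr moved it by 0.11 in yerA-KO but by only -0.002 in F91L and in Q150W. The limma test on log2(FPKM + 1), whose values are scaled by library totals, gave 2251 higher and 460 lower genes in F91L, 1776 and 549 in Q150W, 698 and 489 in yerA-KO, and 76 and 382 for Q150W against F91L. A gene list is therefore described relative to the other genes, and its median under library totals is given where that changed sign.

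The targeted gene was measured first, in every library. In WT, yerA stood at 452, 569 and 472 FPKM. It stood at 244, 512 and 447 FPKM in F91L, at 208, 197 and 178 FPKM in Q150W, and at 494, 538 and 335 FPKM in the libraries labelled yerA-KO. The libraries labelled yerA-KO showed no clear loss of yerA reads, which does not by itself go against a knockout that leaves the transcript. Their mean for yerA was 456 ± 107 FPKM against 498 ± 62.4 in WT (SD, n = 3 each), a ratio of 0.916. The exact two-sided permutation p was 0.7. The log2 fold change was -0.38 (95% interval -0.89 to 0.14; adjusted p = 0.21, edgeR). In Q150W the level of yerA was lower than in WT, at 194 ± 15.1 FPKM, with a log2 fold change of -2.34 ± 0.38 (SE; adjusted p = 0.000235, edgeR) and an exact permutation p of 0.1, the smallest that 3 against 3 allow. The size of that fall depended on the scaling and the test, as it was -1.36 with library totals (adjusted p = 0.00246) and -1.22 with library weights in limma (adjusted p = 7.1e-06). In F91L the mean was 401 ± 140 FPKM and the exact permutation p was 0.4. The log2 fold change of -1.60 ± 0.38 (adjusted p = 0.00305, edgeR) in F91L rested on the scaling, since it was -0.31 and not past the test with library totals (adjusted p = 0.388). Q150W and F91L did not differ past the test with TMM (log2 fold change -0.74, adjusted p = 0.227; exact permutation p of 0.1). They differed without F91L replicate 1 (-1.07, adjusted p = 0.0121), with library totals (-1.04, adjusted p = 0.0475) and with library weights in limma (-1.19, adjusted p = 0.00026).

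**Figure D1:**
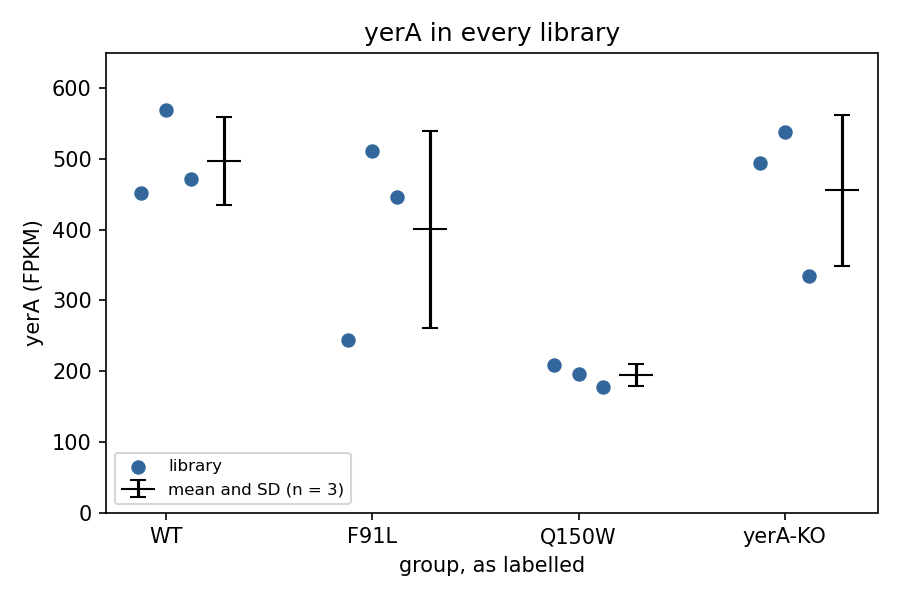
Level of yerA (FPKM, vertical axis) in each library of the 4 groups, with points for single libraries and a bar for the mean with its SD (n = 3). The libraries labelled yerA-KO lie at 335, 494 and 538 FPKM, the lowest of them below the WT range (452 to 569), and those of Q150W between 178 and 208.

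In F91L, the acetoin dehydrogenase operon was among the most reduced. The log2 fold change was -15.90 ± 0.82 (SE) for acoA, -14.44 ± 0.63 for acoB, -13.79 ± 0.59 for acoC and -13.00 ± 0.67 for acoL, and acoA fell from 36465 ± 2101 CPM (counts scaled to TMM-adjusted library size) in WT to 0.595 ± 0.565 (SD, n = 3). The protease gene aprE, which encodes subtilisin, was at least 2164-fold lower and mpr at least 824-fold lower, since F91L held no count of either. Also lower were sboA, the precursor of the bacteriocin subtilosin (-9.38 ± 0.76), the sugar transporter genes msmE (-8.60 ± 0.75) and msmG (-8.05 ± 0.85), and the proline dehydrogenase gene putB (-8.16 ± 0.42). Higher in F91L were cidA (at least 77.9-fold), yybK (at least 61.8-fold), ydzN (at least 12.9-fold), ygzA (at least 11.4-fold), yukD (at least 6.99-fold), yhzF (at least 5.01-fold) and csfG (at least 4.20-fold), none of which had a count in WT. The call of csfG was lost without WT replicate 2 (adjusted p = 0.0501, edgeR). With 1 count in WT, yybL was 213 times higher (counting interval 38.1 to 8409). The gene yybJ rose by 6.55 ± 0.69 on the log2 scale, and hisZ, a regulatory subunit of the first step of histidine synthesis, by 6.63 ± 1.12.

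Of 3991 genes tested in F91L against WT, 1982 passed the threshold, 1041 higher and 941 lower, and 508 of them changed at least 8-fold. With library totals 2647 genes passed, 2211 higher and 436 lower, so the even split depended on the scaling. Of the 34 gene lists, 18 differed from the other genes (camera with a preset correlation), 4 upward and 14 downward. None of these calls held with an estimated correlation, where the smallest adjusted p was 0.36 and 3 lists had an unadjusted p under 0.05, while fry called 26 lists. With library totals the downward lists held more members past the test in the higher direction. Higher and lower members were then 5 and 26 for catabolite controlled genes, 8 and 18 for CodY genes, 6 and 24 for peptide antibiotics, 4 and 6 for extracellular degradation, 8 and 11 for respiration and 2 and 2 for the TCA cycle. For general stress they were 2 and 10, for flagella 4 and 5, for chemotaxis 4 and 5, for biofilm matrix 2 and 7, for iron uptake 1 and 1, for PBSX 5 and 8 and for SPbeta 15 and 13.

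Among genes under carbon catabolite control, 33 of 42 fell in F91L, 2 rose and 7 did not pass (35 lower and 2 higher adjusted over the list alone), with a median log2 fold change of -3.14 (camera adjusted p = 5.1e-23; adjusted p = 0.36 with an estimated correlation). The arginine catabolism genes rocD (-6.01 ± 0.39), rocC (-5.75 ± 0.37), rocA (-5.58 ± 0.37) and rocB (-4.98 ± 0.35) led the list of branched-chain amino acid and CodY genes, of which 20 of 30 fell and none rose (20 and 0 adjusted over the list alone). The median was -2.97 (adjusted p = 7.01e-10, and adjusted p = 0.36 with an estimated correlation). In the list of surfactin and peptide antibiotics, 30 of 45 fell and 3 rose (the same counts adjusted over the list alone), among them the polyketide synthase gene pksL (-5.25 ± 0.34) and the plipastatin synthetase gene ppsD (-5.74 ± 0.39). The median was -2.65 (adjusted p = 6.21e-12, and adjusted p = 0.36 with an estimated correlation). The extracellular degradation list had 8 of 14 lower and 1 higher, the neutral protease gene nprB (6.24 ± 0.53), with a median of -2.07 that was the same with the 2 members at 0 counts set to their bounds (8 and 1 adjusted over the list alone). The list passed (adjusted p = 0.00208, and adjusted p = 0.48 with an estimated correlation).

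Energy metabolism shifted in both directions in F91L. Of 25 respiration and ATP synthase genes, 17 fell and 1 rose (17 and 1 adjusted over the list alone), led by the cytochrome c oxidase genes ctaE (-6.41 ± 0.51), ctaF (-5.83 ± 0.49) and ctaD (-5.44 ± 0.42). The median was -1.84 (adjusted p = 6.64e-07, and adjusted p = 0.48 with an estimated correlation). Of 13 tricarboxylic acid (TCA) cycle genes, 10 fell and 1 rose (10 and 1 adjusted over the list alone), with the malate dehydrogenase gene mdh at -2.79 ± 0.36 and sucD at -3.18 ± 0.45. The TCA list median was -1.26, but 0.02 with library totals (adjusted p = 0.0143; adjusted p = 0.59 with an estimated correlation). Of 10 glycolysis genes 4 rose and 1 fell (5 and 1 adjusted over the list alone), led by the operon repressor gene cggR (3.80 ± 0.35) and the glyceraldehyde-3-phosphate dehydrogenase gene gapA (3.17 ± 0.43). Its median was 1.02 (adjusted p = 0.0214, and adjusted p = 0.59 with an estimated correlation). The glycolysis call was lost without WT replicate 1 (adjusted p = 0.0605), and the TCA call with library totals (adjusted p = 0.0732). Without F91L replicate 1, 9 glycolysis genes were higher, and without WT replicate 3, 6 TCA genes were lower.

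Ribosomal protein genes were higher in F91L: 17 of 43 rose and none fell (16 and 0 adjusted over the list alone), with rpmI at 2.86 ± 0.33 and rplM at 2.30 ± 0.34, and 27 rose without F91L replicate 1. The median was 0.84 (adjusted p = 0.00211, and adjusted p = 0.59 with an estimated correlation). Histidine and tryptophan synthesis had 10 of 16 higher and none lower (12 and 0 adjusted over the list alone), including the prephenate dehydrogenase gene tyrA (4.20 ± 0.33) and hisB (4.39 ± 0.71). The median was 2.25 (adjusted p = 0.00215, and adjusted p = 0.59 with an estimated correlation). Fatty acid and phospholipid synthesis had 8 of 16 higher and 1 lower (8 and 1 adjusted over the list alone), with the phosphatidylserine synthase gene pssA at 3.22 ± 0.32. The median was 1.04 (adjusted p = 0.0164, and adjusted p = 0.59 with an estimated correlation). Purine biosynthesis had 11 of 18 lower and none higher with TMM (12 and 0 adjusted over the list alone) but 4 lower and 5 higher with library totals, where the median was -0.65. With TMM, purF was at -2.79 ± 0.38 and purD at -2.42 ± 0.27, and the median was -2.08 (adjusted p = 0.00211, and adjusted p = 0.59 with an estimated correlation).

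The general stress regulon of SigB had 17 of 23 lower and none higher in F91L (18 and 0 adjusted over the list alone), with ysnF at -5.62 ± 0.54. The median was -2.32 (adjusted p = 3.06e-06, and adjusted p = 0.59 with an estimated correlation). Flagella and motility had 18 of 30 lower and none higher (19 and 0 adjusted over the list alone), including the motility sigma factor gene sigD (-2.22 ± 0.29), and the median of -0.94 turned to 0.42 with library totals (adjusted p = 0.00211, and adjusted p = 0.59 with an estimated correlation). Chemotaxis had 11 of 17 lower and 1 higher (11 and 1 adjusted over the list alone), with cheD at -2.54 ± 0.32, and its median of -1.33 was 0.00 with library totals (adjusted p = 0.00211, and adjusted p = 0.55 with an estimated correlation). Biofilm matrix genes had 13 of 18 lower and none higher (14 and 0 adjusted over the list alone), with the amyloid fibre gene tasA at -3.16 ± 0.54. The median was -1.79 (adjusted p = 0.00338, and adjusted p = 0.59 with an estimated correlation). In iron uptake 8 of 13 fell and none rose (9 and 0 adjusted over the list alone), with dhbF at -2.85 ± 0.46, and the median of -1.20 was 0.06 with library totals (adjusted p = 0.0247, and adjusted p = 0.59 with an estimated correlation). The calls of flagella (adjusted p = 0.0633) and iron uptake (adjusted p = 0.0565) were lost with library totals, and that of iron uptake also without WT replicate 2 (5 genes lower, adjusted p = 0.0719) or F91L replicate 1 (adjusted p = 0.105).

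Of 30 PBSX prophage genes, 19 fell in F91L and none rose (20 and 0 adjusted over the list alone), with xlyA at -2.64 ± 0.32. The median was -1.39 (adjusted p = 0.000649, and adjusted p = 0.59 with an estimated correlation). In SPbeta, 16 of 39 genes fell and 6 rose (the same counts adjusted over the list alone). With 1 library of either group left out, 2 to 5 SPbeta genes rose. The SPbeta median was -1.36 (adjusted p = 0.00856, and adjusted p = 0.64 with an estimated correlation). Beside yerA, the neighbouring yerB (-2.73 ± 0.44) and yerD (-3.20 ± 0.50) fell and yezC rose (2.02 ± 0.41), while the neighbourhood list as a whole, with 4 of 10 lower and 3 higher (2 lower and 5 higher with library totals), did not pass (adjusted p = 0.477). Purine salvage and transport had 5 of 18 higher and 2 lower (adjusted p = 0.441), among them the purine nucleoside phosphorylase gene deoD (2.78 ± 0.36), hprT (3.05 ± 0.41), the purine efflux gene pbuE (3.63 ± 0.53) and adeC (1.38 ± 0.38), the adenine deaminase gene. Lists that did not pass also included competence (7 higher and 3 lower of 21, adjusted p = 0.441), sporulation (1 and 4 of 18, 0.443), the methionine and SAM cycle (5 and 7 of 20, 0.441), the SOS response (4 and 0 of 9, 0.0846), DNA methylation and base repair (3 and 2 of 13, 0.509), purine and urate catabolism (0 and 1 of 11, 0.509), arginine biosynthesis (0 and 2 of 6, 0.441) and the ICEBs1 element (3 and 0 of 12, 0.441). Pyrimidine biosynthesis (1 and 0 of 10, 0.859), SigW genes (2 and 2 of 17, 0.698), anaerobic genes (4 and 10 of 18, 0.138) and nitrogen limitation (2 and 4 of 13, 0.441) did not pass in F91L. The medians of yerA neighbours (1.07), purine and urate catabolism (0.97), the methionine cycle (0.79), sporulation (1.26), arginine biosynthesis (0.14), nitrogen limitation (1.24) and sulfur assimilation (0.75) were above 0 with library totals and below 0 with TMM. The SigW median (0.06) was -0.03 with median-of-ratios scaling, and sporulation (0.09) and nitrogen limitation (0.07) were also above 0 with upper-quartile scaling.

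In Q150W, the acetoin dehydrogenase operon was again far below WT. The log2 fold change was -13.64 ± 0.76 (SE, n = 3 per group) for acoA, -13.60 ± 0.61 for acoB, -12.72 ± 0.57 for acoC and -12.31 ± 0.65 for acoL. Trehalose genes rose: treA, which encodes the hydrolase of trehalose phosphate, by 7.87 ± 0.53, the transporter gene treP by 6.76 ± 0.50 and the repressor gene treR by 6.48 ± 0.46. The glucose transporter gene ptsG rose by 6.91 ± 0.43, from 36.7 ± 6.55 to 4404 ± 723 CPM (SD, n = 3), and nprB by 7.63 ± 0.56. Lower genes by the naming rule were mpr (at least 700.0-fold), nprE at -8.99 ± 0.82, aprE at -8.73 ± 0.69, sboA at -11.55 ± 0.85, putB at -8.83 ± 0.44 and the ornithine aminotransferase gene rocD at -8.33 ± 0.43. Also higher were cidA (at least 34.9-fold), ydcG (6.48 ± 0.53), sipU (6.39 ± 0.49), yuzN (6.37 ± 0.60) and a copy of the duplicated name gswA, which had 1 count in WT and was 301 times higher (counting interval 53.8 to 11880).

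Of 3991 genes tested, 1907 passed in Q150W against WT, 975 higher and 932 lower, and 501 changed at least 8-fold. With library totals 2303 genes passed, 1772 higher and 531 lower. Of the 34 lists 17 passed, 3 upward and 14 downward. None held with an estimated correlation, where the smallest adjusted p was 0.42 and 3 lists had an unadjusted p under 0.05, while fry called 22. With library totals, higher and lower members of the downward lists were 5 and 9 for purine biosynthesis, 0 and 6 for pyrimidine biosynthesis, 8 and 9 for respiration, 5 and 7 for anaerobic genes and 3 and 6 for nitrogen limitation. They were 10 and 26 for catabolite controlled genes, 6 and 19 for CodY genes, 3 and 25 for peptide antibiotics, 4 and 7 for extracellular degradation and 0 and 11 for general stress. For SigW genes they were 1 and 5, for flagella 1 and 6, for chemotaxis 3 and 4 and for SPbeta 7 and 18.

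Ribosomal protein genes were nearly all higher in Q150W, with 40 of 43 past the test and none lower (the same counts adjusted over the list alone), led by rpsD (3.53 ± 0.40) and rpsB (2.84 ± 0.35). The median was 1.69 (adjusted p = 4.09e-10, and adjusted p = 0.59 with an estimated correlation). Glycolysis had 8 of 10 higher and none lower (8 and 0 adjusted over the list alone), with the aldolase gene fbaA at 3.41 ± 0.43 and gapA at 3.18 ± 0.43. The median was 1.5 (adjusted p = 0.00108, and adjusted p = 0.61 with an estimated correlation). Fatty acid and phospholipid synthesis had 12 of 16 higher and 1 lower (13 and 1 adjusted over the list alone), with pssA at 2.49 ± 0.31. The median was 1.25 (adjusted p = 0.00615, and adjusted p = 0.61 with an estimated correlation). Respiration and ATP synthase had 14 of 25 lower and 4 higher (14 and 5 adjusted over the list alone), with ctaE at -5.88 ± 0.50. Its median was -1.11 (adjusted p = 0.00339, and adjusted p = 0.61 with an estimated correlation). Higher glycolysis genes numbered 5 without WT replicate 1 or 3, higher fatty acid genes 7 without WT replicate 1, and lower respiration genes 9 without Q150W replicate 1.

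Both nucleotide pathways were lower in Q150W. Pyrimidine biosynthesis had 8 of 10 lower and none higher (8 and 0 adjusted over the list alone), with the orotate phosphoribosyltransferase gene pyrE at -3.90 ± 0.53 and pyrK at -3.54 ± 0.52. The median was -3.26 (adjusted p = 0.00347, and adjusted p = 0.61 with an estimated correlation). Purine biosynthesis had 12 of 18 lower and 1 higher (12 and 1 adjusted over the list alone), with purN at -3.25 ± 0.36. The median was -2.49 (adjusted p = 0.000976, and adjusted p = 0.61 with an estimated correlation). The anaerobic and fermentation list had 10 of 18 lower and 5 higher (10 and 5 adjusted over the list alone), led by the nitrate reductase genes narI (-8.27 ± 0.67) and narH (-7.13 ± 0.56) and the anaerobic regulator gene fnr (-4.96 ± 0.46). Higher genes of this list numbered 2 to 4 with 1 library of either group left out. The median was -1.71 (adjusted p = 0.00347, and adjusted p = 0.61 with an estimated correlation). Nitrogen limitation genes had 8 of 13 lower and none higher (8 and 0 adjusted over the list alone), including gabP (-4.02 ± 0.45) and glnK (-3.69 ± 0.52). Its median was -2.03 (adjusted p = 0.00615, and adjusted p = 0.43 with an estimated correlation).

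Catabolite controlled genes had 29 of 42 lower and 5 higher in Q150W (the same counts adjusted over the list alone). The median was -2.56 (adjusted p = 3.08e-14, and adjusted p = 0.59 with an estimated correlation). Branched-chain amino acid and CodY genes had 19 of 30 lower and 2 higher (19 and 2 adjusted over the list alone), with rocB at -7.52 ± 0.39. The median was -2.93 (adjusted p = 1.08e-10, and adjusted p = 0.43 with an estimated correlation). Peptide antibiotic genes had 28 of 45 lower and 2 higher (30 and 2 adjusted over the list alone), with pksJ at -6.23 ± 0.35 and ppsC at -6.34 ± 0.40. The median was -2.49 (adjusted p = 4.27e-14, and adjusted p = 0.42 with an estimated correlation). Extracellular degradation had 7 of 14 lower and 1 higher (7 and 1 adjusted over the list alone). Its median was -1.28 (adjusted p = 0.00404, and adjusted p = 0.59 with an estimated correlation). General stress genes had 16 of 23 lower and none higher (16 and 0 adjusted over the list alone), with ysnF at -6.08 ± 0.55 and gsiB at -4.59 ± 0.56. The median was -2.09 (adjusted p = 5.44e-05, and adjusted p = 0.61 with an estimated correlation).

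Cell envelope stress genes of SigW had 11 of 17 lower and none higher in Q150W (12 and 0 adjusted over the list alone), including the flotillin gene floT (-3.27 ± 0.40) and yuaI (-3.02 ± 0.41), and the median of -0.92 was 0.08 with library totals (adjusted p = 0.00404, and adjusted p = 0.61 with an estimated correlation). Flagella and motility had 16 of 30 lower and none higher (20 and 0 adjusted over the list alone), with the flagellin gene hag at -2.80 ± 0.43. The median was -1.0 (adjusted p = 0.00122, and adjusted p = 0.61 with an estimated correlation). Chemotaxis had 9 of 17 lower and 1 higher (9 and 1 adjusted over the list alone), a call lost with library totals (adjusted p = 0.116). The median was -1.33 (adjusted p = 0.0174, and adjusted p = 0.61 with an estimated correlation). In the SPbeta prophage 22 of 39 fell and 3 rose (22 and 3 adjusted over the list alone), with yomL at -4.53 ± 0.44. Its median was -2.05, also with its 2 members at 0 counts set to their bounds (adjusted p = 0.000271, and adjusted p = 0.61 with an estimated correlation).

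Of the neighbours of yerA, yerB (-2.57 ± 0.44), yerC (-2.22 ± 0.42) and yerD (-2.33 ± 0.49) fell in Q150W. The neighbourhood list had 4 of 10 higher and 4 lower, with a median of 0.41, a mean of -0.29 and a downward test that did not pass (adjusted p = 0.825). Higher neighbours numbered 1 to 4 with 1 library of either group left out. Purine salvage had 7 of 18 higher and 3 lower (adjusted p = 0.417), with deoD at 3.17 ± 0.36, pbuE at 3.85 ± 0.54, the adenylate kinase gene adk at 2.41 ± 0.39 and nupN at -3.29 ± 0.52. The TCA cycle (2 higher and 4 lower of 13, adjusted p = 0.554), biofilm matrix (1 and 9 of 18, 0.121), histidine and tryptophan synthesis (2 and 2 of 16, 0.635), PBSX (3 and 6 of 30, 0.944) and iron uptake (0 and 6 of 13, 0.113) did not pass in Q150W. Lower biofilm genes numbered 5 to 10 with 1 library of either group left out. The ICEBs1 list did not pass either (2 higher and 1 lower of 12, adjusted p = 0.873), and its median of -0.10 differed in sign from its mean of 0.22 and its test. With library totals the medians of purine and urate catabolism (0.04), the methionine cycle (0.72), sporulation (0.78), the TCA cycle (0.65), arginine biosynthesis (0.51), iron uptake (0.08), sulfur assimilation (0.70), PBSX (0.82) and ICEBs1 (0.84) turned above 0 in Q150W, that of ICEBs1 also with upper-quartile scaling (0.07).

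In the libraries labelled yerA-KO, where yerA itself was still transcribed near the WT level, the pyruvate transporter genes pftA and pftB rose by 10.50 ± 0.62 and 9.10 ± 0.47 on the log2 scale (SE, n = 3 per group), pftB from 14.8 ± 6.79 to 8029 ± 514 CPM (SD). The maltose transporter gene malP rose by 6.59 ± 0.30, malR by 6.19 ± 0.40, the dicarboxylate transporter gene dctP by 6.53 ± 0.39, licC by 5.73 ± 0.44, ptsG by 5.63 ± 0.36 and bglP by 5.07 ± 0.46, and nprB by 8.77 ± 0.57. Lower were the protease genes nprE (at least 503-fold), mpr (at least 432-fold), aprE (-7.86 ± 0.43) and epr (-7.18 ± 0.61), the unnamed gene BSU_27035 (at least 55.4-fold) and the acetoin genes acoC (-7.70 ± 0.39), acoL (-7.10 ± 0.43), acoA (-6.92 ± 0.30) and acoB (-6.78 ± 0.43). With 2 counts in the libraries labelled yerA-KO, csbD was 109 times lower (counting interval 29.4 to 915). The signal peptide gene phrG, at least 7.45-fold higher, lost its call when any library other than yerA-KO replicate 3 was left out (adjusted p = 0.0683 to 0.0997, edgeR).

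Of 3764 genes tested, 1553 passed in the libraries labelled yerA-KO against WT, 794 higher and 759 lower, and 287 changed at least 8-fold. Without yerA-KO replicate 3, the library with 56.2% of its counts in ssrA, 1828 genes passed. With library totals 1304 passed, 802 higher and 502 lower. Of the 34 lists 12 passed, 5 upward and 7 downward. None held with an estimated correlation, where the smallest adjusted p was 0.22 and 5 lists had an unadjusted p under 0.05, while fry called 21.

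Every pyrimidine biosynthesis gene tested fell in the libraries labelled yerA-KO, 10 of 10 (10 adjusted over the list alone), with pyrC at -6.07 ± 0.49, pyrK at -5.86 ± 0.31 and pyrAA at -5.76 ± 0.39. The median was -4.51 (adjusted p = 3.29e-12, and adjusted p = 0.3 with an estimated correlation). Purine biosynthesis had 11 of 18 lower and 1 higher (13 and 1 adjusted over the list alone), with purD at -4.05 ± 0.27 and purN at -3.61 ± 0.45. The median was -2.51 (adjusted p = 5.05e-05, and adjusted p = 0.58 with an estimated correlation). Ribosomal protein genes had 30 of 43 lower and none higher (the same counts adjusted over the list alone), with rplW at -4.66 ± 0.33 and rpsJ at -4.18 ± 0.32. The median was -2.02 (adjusted p = 8.89e-13, and adjusted p = 0.3 with an estimated correlation). Without yerA-KO replicate 3 the ribosomal median was -1.79 and 30 members were lower.

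In the libraries labelled yerA-KO, glycolysis had 7 of 10 higher and none lower (7 and 0 adjusted over the list alone), with gapA at 4.05 ± 0.34 and the phosphoglucose isomerase gene pgi at 3.49 ± 0.27. Its median was 2.62 (adjusted p = 2.16e-05, and adjusted p = 0.38 with an estimated correlation). The TCA cycle had 12 of 13 higher and 1 lower (12 and 1 adjusted over the list alone), with the fumarase gene fumC at 3.59 ± 0.49 and the aconitase gene citB at 2.40 ± 0.29, and 7 were higher without WT replicate 1 or 3. The median was 1.35 (adjusted p = 0.000628, and adjusted p = 0.3 with an estimated correlation). Respiration and ATP synthase had 15 of 25 lower and 2 higher (17 and 2 adjusted over the list alone), with ctaD at -2.47 ± 0.28 and atpG at -2.04 ± 0.26. The median was -1.12 (adjusted p = 0.000628, and adjusted p = 0.39 with an estimated correlation). Catabolite controlled genes went both ways, 18 higher and 16 lower of 42 (19 and 19 adjusted over the list alone), and did not pass (adjusted p = 0.988), with a median of -0.27 that was 0.07 with library totals.

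Heat shock genes had 10 of 15 higher and 2 lower in the libraries labelled yerA-KO (12 and 2 adjusted over the list alone), with the chaperonin gene groEL at 3.62 ± 0.38 and groES at 3.12 ± 0.30. The median was 1.56 (adjusted p = 0.000158, and adjusted p = 0.22 with an estimated correlation). Iron uptake had 10 of 13 higher and none lower (11 and 0 adjusted over the list alone), with the bacillibactin synthesis gene dhbA at 3.21 ± 0.29. Its median was 1.88 (adjusted p = 0.000158, and adjusted p = 0.3 with an estimated correlation). Sulfur assimilation had 8 of 12 higher and none lower (8 and 1 adjusted over the list alone), with the cystine transporter gene tcyP at 3.19 ± 0.30. The median was 1.61 (adjusted p = 0.000217, and adjusted p = 0.22 with an estimated correlation). General stress genes had 16 of 23 lower and 1 higher (18 and 1 adjusted over the list alone), with gsiB at -6.38 ± 0.59. The median was -1.70 (adjusted p = 8.03e-07, and adjusted p = 0.3 with an estimated correlation). Peptide antibiotic genes had 22 of 44 lower and 11 higher (23 and 11 adjusted over the list alone), with pksL at -4.59 ± 0.27; after removal of a length trend that list did not pass (adjusted p = 0.32). The median was -1.0 (adjusted p = 0.000158, and adjusted p = 0.3 with an estimated correlation). Branched-chain amino acid and CodY genes had 13 of 30 lower and 5 higher (14 and 6 adjusted over the list alone), with rocA at -3.73 ± 0.27 and ilvC at -3.41 ± 0.37. Its median was -0.61 (adjusted p = 0.0249, and adjusted p = 0.69 with an estimated correlation). That call was lost with the replicate block (adjusted p = 0.0564), with library totals (adjusted p = 0.092), without WT replicate 2 (adjusted p = 0.0915) and without yerA-KO replicate 3 (adjusted p = 0.127).

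Near yerA, the DNA ligase gene ligA fell by 1.68 ± 0.29 on the log2 scale and the helicase gene pcrA by 1.44 ± 0.25 in the libraries labelled yerA-KO, the latter not past the test with library totals (-1.13, adjusted p = 0.0646). The neighbourhood list had 3 of 10 lower and none higher (adjusted p = 0.157). Purine salvage had 6 of 18 higher and 5 lower (adjusted p = 0.744), with the GMP reductase gene guaC at -5.06 ± 0.51, the xanthine permease gene pbuX at -3.10 ± 0.32, pbuG at -1.87 ± 0.27 and deoD at 2.49 ± 0.27. Flagella (3 higher and 14 lower of 30, adjusted p = 0.0621), chemotaxis (1 and 6 of 17, 0.0738), biofilm matrix (0 and 6 of 17, 0.116), SPbeta (0 and 4 of 39, 0.374) and nitrogen limitation (4 and 1 of 13, 0.48) did not pass in these libraries. With 1 library of either group left out, 8 to 17 flagella genes were lower and 1 to 2 higher. The extracellular degradation list (4 higher and 5 lower of 13, adjusted p = 0.113) had a median of 0.32 and a mean of -2.16, PBSX (6 and 3 of 30, 0.758) a median of -0.10 and a mean of 0.05, and purine and urate catabolism (0 and 1 of 10, 0.988) a median of 0.11 and a mean of -0.13, so that the signs differed within each. With library totals the medians of SigW genes (0.10), anaerobic genes (0.10) and PBSX (0.25) were above 0.

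**Figure D2:**
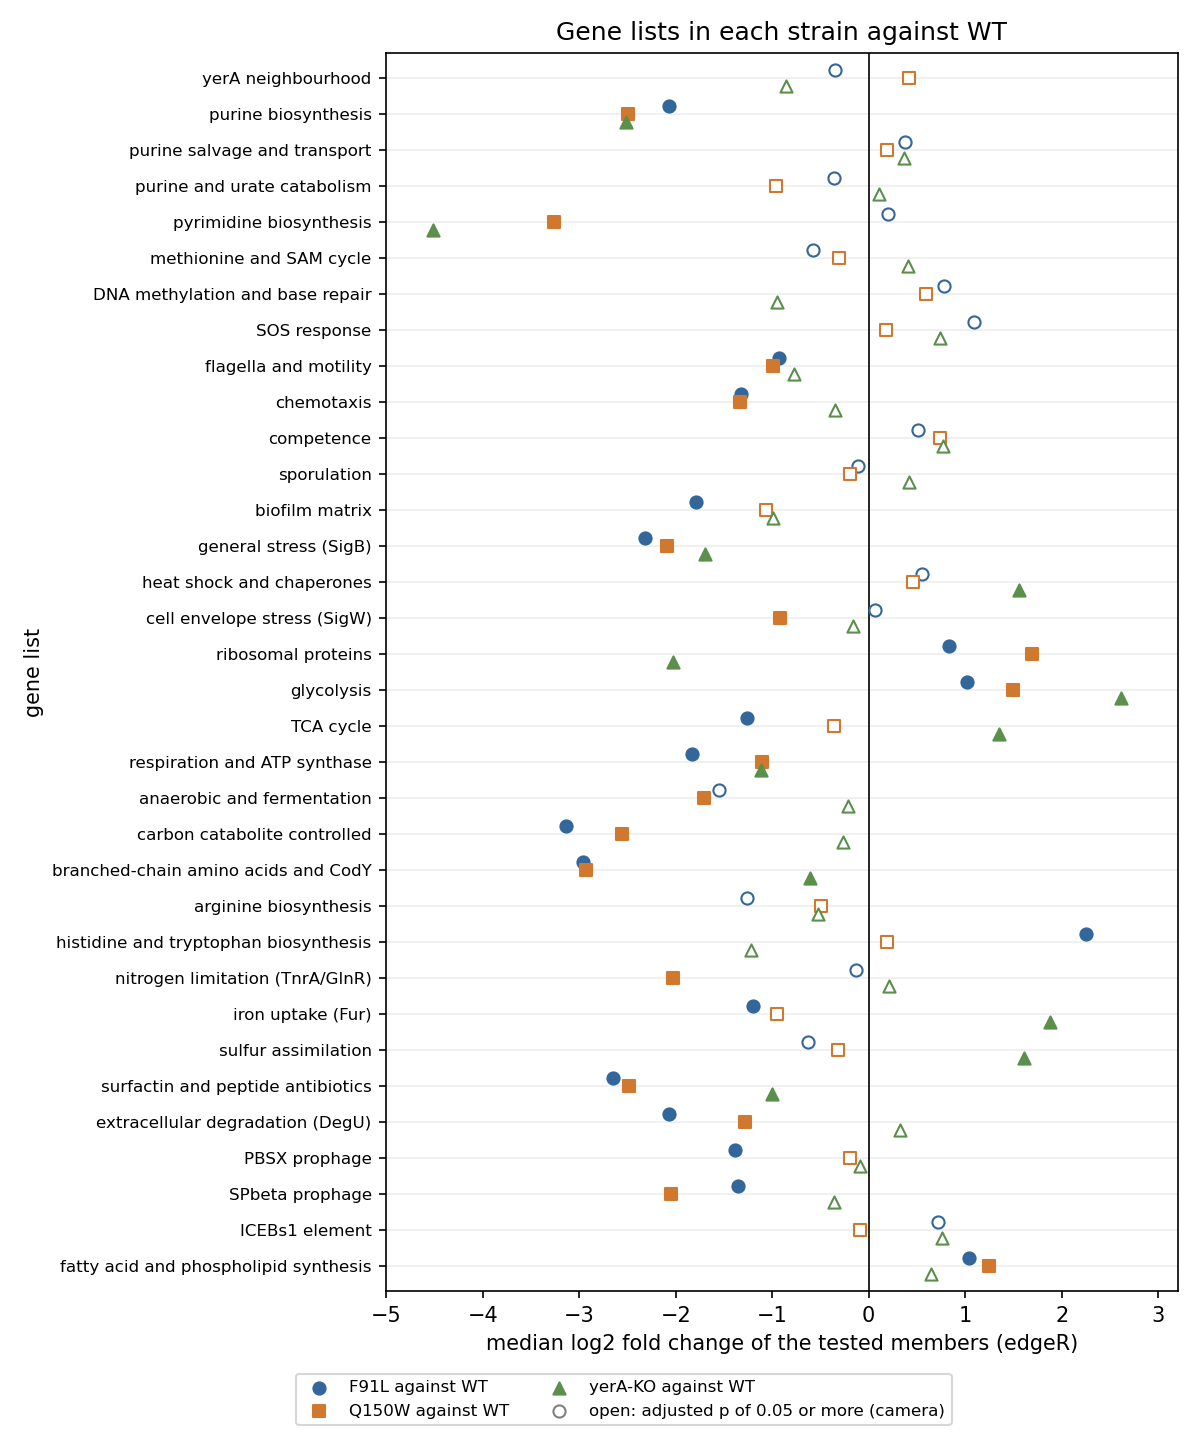
Median log2 fold change (edgeR, horizontal axis) of the tested members of each of the 34 gene lists (vertical axis) in F91L, Q150W and the libraries labelled yerA-KO, each against WT with n = 3 per group; filled symbols passed the camera test with its preset correlation, and none passed with an estimated one. Ribosomal proteins lie at 0.84 in F91L, 1.69 in Q150W and -2.02 in the libraries labelled yerA-KO, in which yerA was still transcribed, and among filled symbols the medians of flagella, chemotaxis, the TCA cycle and iron uptake in F91L and of SigW genes in Q150W were at or above 0 with library totals.

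In Q150W set directly against F91L, the log2 fold change was -4.50 ± 0.57 (SE, n = 3 per group) for narI, -4.36 ± 0.75 for narJ and -4.05 ± 0.49 for narH, all parts of the nitrate reductase operon, and -3.86 ± 0.62 for the regulator gene arfM and -4.44 ± 0.77 for BSU_18596. Higher in Q150W were pdhB, a subunit gene of pyruvate dehydrogenase (2.84 ± 0.33), the ribose operon repressor gene rbsR (2.79 ± 0.48), cutJ (3.19 ± 0.49), cutR (2.89 ± 0.38) and cutI (2.79 ± 0.58). Of 3991 genes tested 330 passed, 144 higher and 186 lower, and 81 higher and 385 lower with library totals. The count fell to 162 without F91L replicate 3, 166 without Q150W replicate 1, 145 without Q150W replicate 2 and 208 without Q150W replicate 3. Of the 34 lists 14 passed, 7 in each direction; none held with an estimated correlation, where the smallest adjusted p was 0.16 and 4 lists had an unadjusted p under 0.05, and fry called 6.

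Pyrimidine biosynthesis was lower in Q150W than in F91L in 9 of 10 genes (10 adjusted over the list alone), with pyrK at -3.58 ± 0.52. The median was -3.05 (adjusted p = 1.23e-10, and adjusted p = 0.37 with an estimated correlation). Histidine and tryptophan synthesis had 8 of 16 lower and none higher (11 and 0 adjusted over the list alone), with hisH at -3.69 ± 0.66 and hisB at -3.66 ± 0.65. The median was -2.03 (adjusted p = 6.97e-08, and adjusted p = 0.27 with an estimated correlation). SigW genes had 9 of 17 lower and none higher (14 and 0 adjusted over the list alone), with yuaI at -2.95 ± 0.40 and floT at -2.49 ± 0.39. The median was -1.42 (adjusted p = 8.26e-12, and adjusted p = 0.19 with an estimated correlation). Nitrogen limitation had 4 of 13 lower and none higher (8 and 0 adjusted over the list alone), with glnK at -3.42 ± 0.52. Its median was -1.09 (adjusted p = 7.25e-05, and adjusted p = 0.16 with an estimated correlation). Anaerobic and fermentation genes had 8 of 18 lower and 1 higher (8 and 1 adjusted over the list alone). The median was -0.74 (adjusted p = 1.88e-05, and adjusted p = 0.52 with an estimated correlation). Heat shock genes had 3 of 15 lower and none higher (5 and 0 adjusted over the list alone), led by the ATPase gene clpE (-3.15 ± 0.33). The median was -0.65 (adjusted p = 0.0124, and adjusted p = 0.44 with an estimated correlation). SPbeta had 4 of 39 lower and none higher (5 and 0 adjusted over the list alone). The median was -0.33 (adjusted p = 0.02, and adjusted p = 0.73 with an estimated correlation). Lower SPbeta genes numbered 0 without F91L replicate 2 or 3 or Q150W replicate 2 or 3, and 1 without Q150W replicate 1. Lower heat shock genes numbered 7 without F91L replicate 1 and 1 when any other library of the 2 groups was left out. Lower genes numbered 5 for histidine and tryptophan synthesis without F91L replicate 2, and without Q150W replicate 2 they numbered 4 there, 5 for SigW and 2 for nitrogen limitation.

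Higher in Q150W than in F91L were PBSX prophage genes, 13 of 30 with none lower (24 and 0 adjusted over the list alone), with xkdQ at 1.55 ± 0.28 and xlyA at 1.59 ± 0.31. Its median was 1.24 (adjusted p = 1.85e-14, and adjusted p = 0.27 with an estimated correlation). Ribosomal proteins had 8 of 43 higher and none lower (17 and 0 adjusted over the list alone), with rpsB at 1.93 ± 0.34. The median was 0.85 (adjusted p = 1.23e-10, and adjusted p = 0.37 with an estimated correlation). Respiration and ATP synthase had 5 of 25 higher and 1 lower (5 and 1 adjusted over the list alone), with atpD at 2.17 ± 0.38. The median was 0.66 (adjusted p = 5.6e-06, and adjusted p = 0.44 with an estimated correlation). Catabolite controlled genes had 11 of 42 higher and 1 lower (15 and 2 adjusted over the list alone), the lower one being the glycerol-3-phosphate dehydrogenase gene glpD (-3.78 ± 0.48). The median was 0.73 (adjusted p = 1.09e-07, and adjusted p = 0.52 with an estimated correlation). The TCA cycle had 2 of 13 higher (5 adjusted over the list alone). Its median was 0.85 (adjusted p = 0.000141, and adjusted p = 0.44 with an estimated correlation). Biofilm matrix had 1 of 18 higher (0 adjusted over the list alone). The median was 0.94 (adjusted p = 0.00366, and adjusted p = 0.52 with an estimated correlation). Glycolysis had 1 of 10 higher (1 adjusted over the list alone). The median was 0.48 (adjusted p = 0.0456, and adjusted p = 0.66 with an estimated correlation). Many of these counts depended on 1 library. When any 1 of the 6 libraries was left out, no biofilm gene was higher. Higher TCA genes numbered 4 without F91L replicate 1, 1 without F91L replicate 3 or Q150W replicate 3, and 0 without Q150W replicate 1 or 2. Higher glycolysis genes numbered 2 without F91L replicate 1 and 0 without F91L replicate 2 or 3 or Q150W replicate 2 or 3. Higher PBSX genes numbered 5 without F91L replicate 3 or Q150W replicate 3. Ribosomal genes numbered 3 without F91L replicate 2 or 3, 5 without Q150W replicate 1 and 2 without Q150W replicate 2. Catabolite controlled genes numbered 5 without F91L replicate 3 or Q150W replicate 1 or 2, and 4 without Q150W replicate 3.

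Leaving out single libraries ended some of these list calls between Q150W and F91L. Biofilm matrix was lost without F91L replicate 1 (adjusted p = 0.0941), heat shock without F91L replicate 2 (0.0562) or 3 (0.0589), and SPbeta without F91L replicate 2 (0.104), F91L replicate 3 (0.0852) or Q150W replicate 3 (0.539). Glycolysis was lost without F91L replicate 1 (0.379), Q150W replicate 2 (0.0512) or Q150W replicate 3 (0.0929), with library totals (0.067) and after removal of a length trend (0.127). With fry, glycolysis (0.224), SPbeta (0.324), biofilm matrix (0.117), catabolite controlled genes (0.118), anaerobic genes (0.105), pyrimidine biosynthesis (0.0666), heat shock, the TCA cycle and respiration (0.0525 each) did not pass. Purine salvage (median -0.04, mean -0.08, test upward, adjusted p = 0.739) and sporulation (median -0.23, mean -0.07, test upward, adjusted p = 0.813) did not pass in the direct comparison. With library totals the medians of yerA neighbours (-0.23), DNA methylation and repair (-0.34), chemotaxis (-0.16), SigB genes (-0.11), sulfur assimilation (-0.08), extracellular degradation (-0.23) and fatty acid synthesis (-0.21), none of which passed, were below 0 and with TMM above it.

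F91L and Q150W shared many calls against WT: 742 genes were higher in both and 746 lower in both, 5 went in opposite directions, and the log2 fold changes correlated across genes with r = 0.89. Lists drawn independently would share 254 higher and 220 lower genes. F91L shared 362 higher and 432 lower genes with the libraries labelled yerA-KO, in which yerA was still transcribed, with 152 opposite (208 and 190 for independent lists; r = 0.51). Q150W shared 381 higher and 445 lower with them, with 164 opposite (198 and 189 for independent lists; r = 0.55). Unchanged groups simulated against the shared WT libraries gave 0 shared calls in 20 simulations, with r = 0.56 for F91L and Q150W and r = 0.55 for the other pairs. No gene was changed in these simulations, so hardly any call was possible. The 0 therefore does not measure what shared controls add where many genes are called. The observed r of the pairs with yerA-KO (0.51 and 0.55) was no higher than the simulated r. With no gene changed, the simulated r reflects only noise and the shared controls. It therefore does not show how much of the observed r the shared controls gave. The covariance was 4.39 against a simulated 0.19 for F91L and Q150W, 1.98 against 0.18 for F91L and yerA-KO, and 2.15 against 0.18 for Q150W and yerA-KO. The 3 WT libraries could not be split, so part of the excess of shared calls may come from the shared controls, and genes are not independent replicates.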

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

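The tests of label exchange, adeC reads, a remaining transcript, scaling, growth stage, gene length and the single library were chosen only after the result was seen, and the counts over other splits of the libraries before it.

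Gene lists, 8 in number, differed between the effects of Q150W and F91L in the direct test while passing against WT in 1 of these strains and not in the other. The camera adjusted p was 1.23e-10 for pyrimidine biosynthesis, 0.00366 for biofilm matrix, 8.26e-12 for SigW genes, 0.000141 for the TCA cycle, 1.88e-05 for anaerobic and fermentation genes, 6.97e-08 for histidine and tryptophan synthesis, 7.25e-05 for nitrogen limitation and 1.85e-14 for PBSX. With an estimated correlation the adjusted p of these lists ran from 0.16 to 0.52, so none passed. Histidine synthesis varied between the F91L libraries, with hisZ at 87.2 ± 80.4 CPM (SD, n = 3).

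The libraries labelled yerA-KO held yerA reads near the level of WT. On the TMM scale yerA stood at 676, 662 and 828 CPM in them, each below the 885, 1013 and 912 CPM of WT. Reads shared with adeC, the other adenine deaminase gene, stay open. The adeC level reached at most 0.0644 of that of yerA in these libraries, but it was measured after reads were assigned to genes. Reads of adeC counted for yerA would therefore not show in it. A knockout that leaves most of the transcript cannot be told apart from an intact gene with these data, since counts of whole genes hold no position and the mean level was 0.916 of WT. For the same reason an exchange of labels with another group stays open: the lowest yerA level of the 12 libraries was 37.8% of the WT median, but a knockout that keeps its transcript could carry any label. A strain that was not the intended one also stays open and was not tested, so every direction given for these libraries is that of the label and not of a shown loss of yerA.

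Genes under carbon catabolite control were lower in F91L and Q150W, with a list mean of 8.80 ± 0.09 log2 CPM in WT, 4.62 ± 0.83 in F91L, 5.52 ± 0.18 in Q150W and 8.70 ± 0.13 in the libraries labelled yerA-KO (SD, n = 3). Neither list call held with an estimated correlation (camera adjusted p = 0.36 in F91L and 0.59 in Q150W). The SD of F91L came from replicate 1, at 3.66 against 5.10 and 5.11. Scaling was tested first on library totals, where the list's upper quartile was -0.13 in F91L but 0.84 in Q150W, although the list medians were -1.83 and -1.55, so scaling stays open as part of the fall. A further comparison, made because that test had left the matter open, set the list median -2.65 (SE 0.91) from that of all genes in Q150W and -3.38 (SE 0.91) in F91L. Both SEs run over genes resampled as if independent, not over cultures. A factor per library moves every gene alike and cannot alter these differences. These differences could not come out otherwise under any such factor and so do not test scaling. They repeat the list test and leave open how much of the fall against WT itself came from scaling. Growth stage cannot be told apart from genotype, because the labels do not say which cultures were grown together. WT lay 5.01 times the largest within-group SD above F91L (20.2 times without F91L replicate 1), a gap that either could give. An effect of the substitutions is the biological explanation that the design names, and it remains a hypothesis beside growth stage. Scaling also stays open for the size of the fall against WT.

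Ribosomal protein genes were lower in the libraries labelled yerA-KO, in which yerA was still transcribed, and higher in F91L and Q150W. None of these list calls held with an estimated correlation (camera adjusted p = 0.3, 0.59 and 0.59). A length bias was argued against as the whole cause, since the median difference between a member and the median of 20 other genes of its length was -1.91 (SE 0.32). Those other genes had a median of -0.33, against -2.02 for the list. The SE runs over genes resampled as if independent, not over cultures. It may understate the spread, as the estimated correlation within the list was 0.152. The single library with most reads in ssrA did not account for it, since without yerA-KO replicate 3 the upper quartile of the list was -0.45. Over all genes, log2 fold change correlated with gene length at 0.149 in the libraries labelled yerA-KO, -0.143 in F91L and -0.044 in Q150W (Spearman). A part of the shift due to length therefore stays open. Growth stage was not separable here either, and no biological explanation was tested.

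Over the splits of 6 libraries into groups of 3, 1 of 10 gave as many genes as the real one in each comparison, namely the real split itself. The real counts were 1982 for F91L, 1907 for Q150W and 1553 for yerA-KO against WT and 330 for Q150W against F91L. The highest other split gave 0 genes each time with edgeR, and 138, 297, 467 and 317 genes at an unadjusted p under 0.05. With 10 splits the share cannot fall under 0.05. Each other split mixed libraries of both compared groups, so their difference entered the spread within groups and calls were hardly possible. The 0 therefore does not test whether the real counts arose by chance.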

How the results depend on the processing

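Limma on log2(FPKM + 1), library totals, upper-quartile scaling, TMM without 3 abundant RNAs, the fit of 12 libraries, the length minimum and the length-trend test were added after seeing the data. The named genes other than yerA, narrowed after their stability had been seen, kept direction and side of the threshold in 7357 of 7510 re-tests, with 149 weaker and 4 reversed. Without the narrowing, 12986 of 13744 re-tests were the same, 475 weaker, 204 stronger and 79 reversed, 12 of these in genes past the threshold, again without yerA. The yerA level in the 4 comparisons was the same in 82 of 91 re-tests, weaker in 5, stronger in 3 and reversed in 1, and in Q150W it passed in each of them, at -2.44 to -1.22. List calls were the same in 700 of 793 re-tests and weaker in 93.

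Reversed values were fhuG in F91L (0.24 with library weights), yerA in the libraries labelled yerA-KO (0.083 with library weights) and gapB in those libraries (0.15 with quantile normalization, 0.26 with library weights, 0.051 with library totals); none of these passed there. Library weights in limma raised the counts to 3090 (F91L), 3030 (Q150W), 2651 (yerA-KO) and 1187 (Q150W against F91L), and the shared calls to 2627 (F91L and Q150W), 1665 (F91L and yerA-KO) and 1649 (Q150W and yerA-KO). Q150W against F91L gave 515 genes with a pseudocount of 5 and 642 with DESeq2. The level of yerA in F91L missed the threshold at -0.37 with pseudocounts of 0.1, 1 and 5, at -0.032 with library weights and at -0.31 with library totals, and between Q150W and F91L it passed at -1.19 with library weights and -1.04 with library totals. With an estimated correlation 0 lists passed in each comparison, and with fry 21 in yerA-KO and 6 between Q150W and F91L. The preset correlation was 0.01, against an estimated 0.446 for catabolite controlled genes in F91L and 0.942 for pyrimidine biosynthesis between Q150W and F91L. For nitrogen limitation between Q150W and F91L the estimate was 0.005, yet the unadjusted camera p rose from 1.92e-05 to 0.00458. A higher estimated correlation therefore cannot account for every lost call. The cause of these shifts was not tested.

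Without single libraries, genes changed ranged from 1653 to 1848 (F91L), 1553 to 1819 (Q150W), 1097 to 1828 (yerA-KO) and 145 to 354 (Q150W against F91L). Over the same omissions yerA ranged from -1.80 to -1.24, -2.42 to -2.20, -0.48 to -0.27 and -1.07 to -0.51, in that order, and lists from 17 to 18, 17 to 18, 12 to 15 and 13 to 15. Shared calls ranged from 1198 to 1488 (F91L and Q150W), 554 to 847 (F91L and yerA-KO) and 563 to 896 (Q150W and yerA-KO). The direct count moved by over 1.5 times without F91L replicate 3 (162) and without Q150W replicate 1 (166), 2 (145) or 3 (208), and yerA passed there without F91L replicate 1 (-1.07). Fewer libraries per group lower the power by construction.

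The shared replicate numbers did not pair the libraries: 3 of 18 correlations between libraries of the same number were above 0.1 (-0.62 to 0.3), and 1 of 12 libraries correlated best with its own number. Libraries of different numbers reached 0.6 (WT replicate 2 with Q150W replicate 3) and 0.61 (Q150W replicate 3 with yerA-KO replicate 1). Others went down to -0.48 (WT replicate 2 with yerA-KO replicate 3). A block by replicate number cannot remove such structure. The replicate block gave 1824, 1736, 1471 and 252 genes and 18, 17, 11 and 14 lists. The comparison of yerA-KO already held 2 groups, so restricting the fit to the compared groups gave no further value there.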

Other observations

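The gene groups in this part were chosen after their values were seen. Their counts and medians are those with TMM and were not recomputed as groups with library totals. In F91L, library totals moved log2 fold changes by 1.37 at the median. The TMM medians there were only -0.05 for aminoacyl-tRNA synthetase and -0.04 for pyruvate dehydrogenase genes, so their signs and counts may depend on the scaling.

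The manganese transporter operon mntABCD was lower in all 3 strains against WT, with 4 of 4 genes past the threshold in each and medians of -4.99 in F91L, -5.07 in Q150W and -6.11 in the libraries labelled yerA-KO, in which yerA was still transcribed. The log2 fold change of mntD was -5.07 ± 0.39 (SE, n = 3 per group; adjusted p = 3.58e-07, edgeR), -5.37 ± 0.39 and -6.47 ± 0.34. Maltodextrin uptake and use genes were lower in 8 of 8 in each strain, with medians of -5.32, -4.47 and -1.35. Trehalose genes were higher in 3 of 3 in each, with medians of 5.72, 6.76 and 3.51. The 3 comparisons used the same WT libraries, so agreement between the strains is not independent and may be a trait of those libraries.

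The gluconeogenic genes gapB and pckA were lower in F91L (-7.48 ± 0.39 and -5.25 ± 0.50) and in Q150W (-7.91 ± 0.40 and -5.15 ± 0.50). In the libraries labelled yerA-KO neither passed, and gapB was at -0.31 ± 0.26 (adjusted p = 0.363, edgeR), a sign that turned with library totals (0.051). The glycine cleavage genes were lower in 3 of 3 in F91L and Q150W and in 2 of 3 in the libraries labelled yerA-KO, and higher in Q150W than in F91L in 3 of 3. Pyruvate dehydrogenase genes were higher in Q150W in 4 of 4 against WT (median 2.55; 1 of 4 in F91L) and in 4 of 4 against F91L (median 2.50), with pdhA at 2.67 ± 0.30 in the latter. Aminoacyl-tRNA synthetase genes were higher in Q150W than in F91L in 12 of 23 and lower in none (against WT, 4 higher and 7 lower in F91L and 13 higher and 0 lower in Q150W), including glyS (2.44 ± 0.35), glyQ (2.39 ± 0.28), valS (1.90 ± 0.32) and alaS (1.86 ± 0.29).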
